A study of Mus musculus with 10 samples.

How the data were processed

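RNA was sequenced from 10 sorted cell samples, 5 from pancreas and 5 from pancreatic tumours, with 1 library each. Per the labels' protocols, tissue was made into single cells with hyaluronidase and collagenase (pancreas) or with a tumour dissociation kit (tumours), red cells were lysed, dead cells removed, and cells stained with a fluorescent antibody against the nerve growth factor receptor and sorted. Total RNA was extracted with Trizol, and 2 µg per sample went into a NEBNext Ultra library, per the labels' protocols. That kit does not mark the strand of a transcript. Groups and replicate numbers were taken from the sample titles, and each column of the table was matched to its sample through the code in the sample's description. The codes are CTL for the pancreas samples and COCUL for the tumour samples, and the labels do not explain them. COCUL could stand for co-culture, which the protocols of the labels do not mention.

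The deposited values are estimated counts, 1 column per sample, for 55401 genes. Per the submitters' processing notes, HISAT, HISAT2 and HTSeq were used with the mm10 build, and their versions, the settings of the counting, its strand setting, the annotation release and any filter are not given in the sources used here. The values were whole numbers with a different total per library, and rounding changed nothing. Genes at exactly 4 counts were 1.69 to 2.07 times as frequent per library as their neighbours, with smaller excesses at 8 and 12, so a sequenced fragment seems to add several counts and the number of fragments is unknown. For that reason no counting interval is given, and counts divided by 4 were tried as an alternative chosen after seeing the data. No row lacked a gene name and 0 columns belonged to no sample.

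Of the 55401 gene identifiers 55141 were found in GENCODE mouse release M21 (54349 with the same version), which supplied biotypes and mm10 coordinates. The lncRNA class took in lincRNA, antisense, processed transcript, sense intronic, sense overlapping and related biotypes. Before the data were examined, 47 gene lists were fixed, 21 of them cell type markers, with 640 members. Of these 624 were found under their symbol and 12 histone genes through a newer symbol, and 4 were not matched (Ahsp, Cytor, and the older symbols Cyr61 and Ctgf, whose current names Ccn1 and Ccn2 were also listed). A symbol with several identifiers was represented by the most abundant one.

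Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 17548. Libraries were scaled with TMM factors, 0.960 to 0.972 in pancreas and 1.03 to 1.04 in tumour. Tumour was compared with pancreas by the edgeR 4.0.16 quasi-likelihood F test with robust dispersions in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Directions of changed lncRNA and protein-coding genes were compared by Fisher's exact test. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over 40 lists, and again with an estimated correlation and with fry. Marker sums were CPM relative to total counts, compared as log2(CPM + 1) by the exact two-sided permutation test over all 252 assignments of 10 libraries to 5 and 5 (scipy 1.17.1), adjusted over 21 lists. Shares of counts were tested likewise, and gave adjusted p-values of 0.00794. Overlaps of exons were found with bedtools 2.31.1, and figures were drawn with matplotlib.

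Depth was 58242278 to 89816499 estimated counts per library. Duplicated libraries were looked for by chi-square tests of each pair on counts divided by 4, over genes with a mean of at least 100 counts. Chi-square per degree of freedom was 3.59 to 44.0 within pancreas and 3.00 to 6.16 within tumour, so no pair was closer than sampling noise and each library counted as 1 replicate. On simulated counts for 17548 genes in the tumour against pancreas design, with 200 changed genes seeded, the test recovered 59.7% of genes changed 1.5-fold, 64.2% of those changed 2-fold and 83.3% of those changed 4-fold, and called 10 of 16430 unchanged genes. Camera called 0 of 39 simulated lists without change, and the raised list of 12 genes was called. Simulated genes were drawn independently, and far fewer were changed than in the data. So this does not check camera on lists with correlated members, such as the mitochondrially encoded genes (estimated correlation 0.829).

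Named genes followed a rule set before the data were examined: Ngfr, Pvt1, Tdo2 and Trp53 always among others, then the 10 highest and 10 lowest fold changes among called genes with a mean of at least 5 CPM, no overlap between groups and a symbol that is not a clone or predicted-gene name. The rule went on with the 5 highest and 5 lowest lncRNA genes with a mean of at least 1 CPM, clone names allowed, and up to 4 called members of each list in order of adjusted p, or the most abundant members where fewer than 2 were called. Results of some genes under this rule are not reported here. Alternatives covered the scaling (RLE, upper quartile, library size only), the low-count filter, DESeq2 1.42.0 and limma-voom in place of edgeR, the replicate number as a block, each library left out in turn, stricter thresholds, the set test, and the scale and members of the marker sums. Offsets for GC content and transcript length were added after seeing the data, with values for 99.9% of tested genes. Single fragments and reads were not analysed here.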

Results

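Gene expression was measured by RNA sequencing in 10 libraries of mouse cells that the submitters describe as Schwann cells, the glia of peripheral nerves. The cells were sorted with an antibody against the nerve growth factor receptor, encoded by Ngfr, from C57BL/6 KPC mice, a model of pancreatic ductal adenocarcinoma. In this inducible form tamoxifen switches the model on. The 5 tumour libraries came from pancreatic tumours of mice given tamoxifen from 6 weeks of age (20 mg/kg on 5 days). The 5 pancreas libraries came from the pancreas of mice without induction. All were taken at 4 months of age. The series is about long noncoding RNAs (lncRNAs) of tumour-associated Schwann cells and a metabolic, immune-resistant environment, so the tumour libraries were compared with the pancreas libraries. Pancreas and tumour were digested with different enzymes, so digestion coincided with group in all libraries. The sample descriptions code the tumour samples as COCUL and the pancreas samples as CTL without explanation. If COCUL stands for co-culture, tumour values below would be those of cultured cells, and pancreas values could be those of cultured controls. Total estimated counts ran from 60622336 to 89816499 in the pancreas libraries and from 58242278 to 84194616 in the tumour libraries. Per library, 21963 to 23529 genes were above 0. Below, levels are TMM-scaled CPM (counts scaled to a common library total) as mean ± SD over 5 libraries of a group, and log2 fold changes are tumour minus pancreas ± SE, unless stated otherwise.

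The gene of the sort antigen lay near the floor in both groups. Ngfr lies on chromosome 11 at 95568818 to 95587735 in mm10 (ENSMUSG00000000120.6). It had 4 to 22 counts per pancreas library and 0 to 14 per tumour library, or 0.133 ± 0.0931 and 0.0669 ± 0.102 CPM, too few to be tested. Of the 10 listed lineage genes 5 could be tested, of which 2 were higher in tumour and none lower (camera adjusted p = 0.569). Sox5, a transcription factor, was 16.6-fold higher, at 0.375 ± 0.303 CPM in pancreas and 6.36 ± 1.05 in tumour, and the neuregulin receptor gene Erbb3 rose from 2.10 ± 0.809 to 3.70 ± 0.373 CPM. The myelinating list had 2 members higher and 3 lower of 9 (adjusted p = 0.593). The myelin lipid enzyme gene Fa2h (log2 fold change 4.58 ± 0.38) and Mal (1.86 ± 0.16) were higher, and the myelin protein gene Pmp22 was slightly lower (-0.26 ± 0.07, adjusted p = 0.00515). The non-myelinating list had 2 members higher and 3 lower of 6 (adjusted p = 0.893). The adhesion molecule gene Ncam1 was at 102 ± 2.98 and 205 ± 8.51 CPM and Apod at 605 ± 381 and 16.7 ± 2.75 CPM. The repair list had 4 higher and 2 lower of 8 (adjusted p = 0.990). Among them were the cytokine gene Lif (0.87 ± 0.08), the growth factor gene Btc (1.54 ± 0.18), Jun (-0.91 ± 0.07) and the neurotrophin gene Bdnf (-2.93 ± 0.23). For these Schwann lists median, mean and camera direction differed in sign for all but the lineage list. Pmp22 lost its call when libraries were scaled by size only (adjusted p = 0.0758).

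Summed over each marker list as a share of all counts, 12 of 21 cell type lists were lower and 3 higher in tumour, each at the smallest exact permutation p of 0.00794 (two-sided, n = 5 against 5, adjusted p = 0.0111). For these 15 lists every library of one group lay beyond every library of the other. Fibroblast markers summed to 578 ± 40.5 CPM in pancreas and 132 ± 9.81 in tumour, and non-myelinating Schwann markers to 733 ± 370 and 310 ± 10.3. The latter reached 1145 and 1120 CPM in pancreas replicates 3 and 4 against 366 to 533 in the other pancreas libraries, mostly through Apod (1029 and 1000 against 214 to 411). Pericyte and smooth muscle markers summed to 786 ± 58.0 and 580 ± 6.95, and endothelial markers to 365 ± 18.2 and 223 ± 4.58. Ductal epithelial (102 ± 10.1 and 45.3 ± 1.37), repair Schwann (169 ± 10 and 141 ± 4.16), neuronal (42.5 ± 4.36 and 7.34 ± 0.746) and mast cell markers (30.5 ± 3.49 and 10.2 ± 1.37) were lower as well. So were 4 lists near the floor, those of B and plasma cells (5.14 ± 1.41 and 0.482 ± 0.158), neutrophils (3.65 ± 0.911 and 0.373 ± 0.0694), endocrine cells (1.68 ± 0.493 and 0.474 ± 0.237) and mesothelial cells (1.22 ± 0.219 and 0.303 ± 0.144). Adipocyte markers, mostly the nuclear receptor gene Pparg, were higher (21.9 ± 1.01 and 43.8 ± 2.01). Acinar (1.33 ± 0.305 and 2.72 ± 0.313) and T and natural killer cell markers (0.449 ± 0.157 and 1.30 ± 0.369) were higher too, but also near the floor. A single gene held 74.4% of the acinar sum and 81.1% of the T and natural killer cell sum. The remaining 6 lists did not pass with all libraries. Neoplastic epithelium markers summed to 1063 ± 77.8 and 1203 ± 79.4 CPM (exact adjusted p = 0.0521), and passed without pancreas replicate 4 or tumour replicate 5 (exact adjusted p = 0.0417 each). Schwann lineage markers summed to 368 ± 38.0 and 386 ± 15.4 (0.398). Myelinating Schwann markers summed to 169 ± 17.4 and 176 ± 5.50 (0.491), macrophage markers to 28.6 ± 9.26 and 28.1 ± 1.04 (0.905). Dendritic cell markers summed to 1.73 ± 0.347 and 1.92 ± 0.666 (0.708) and erythroid markers to 0.167 ± 0.0846 and 0.233 ± 0.0545 (0.216). Single genes carried many of these sums. Cryab, a small heat shock protein gene, held 97.9% of the Schwann lineage sum, Gata2 97.1% of the mast cell sum and Tubb3 93.2% of the neuronal sum. Without its most abundant member the direction of the sum turned for the acinar, neuronal, neoplastic epithelium, non-myelinating Schwann, repair Schwann and T and natural killer cell lists. The Schwann lineage (log2 difference 1.46), myelinating Schwann (0.54) and macrophage sums (1.00) were then higher in tumour (exact adjusted p = 0.0111 each). Those of B and plasma cells (exact adjusted p = 0.193) and mesothelial cells (0.0784) no longer passed.

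**Figure D1:**
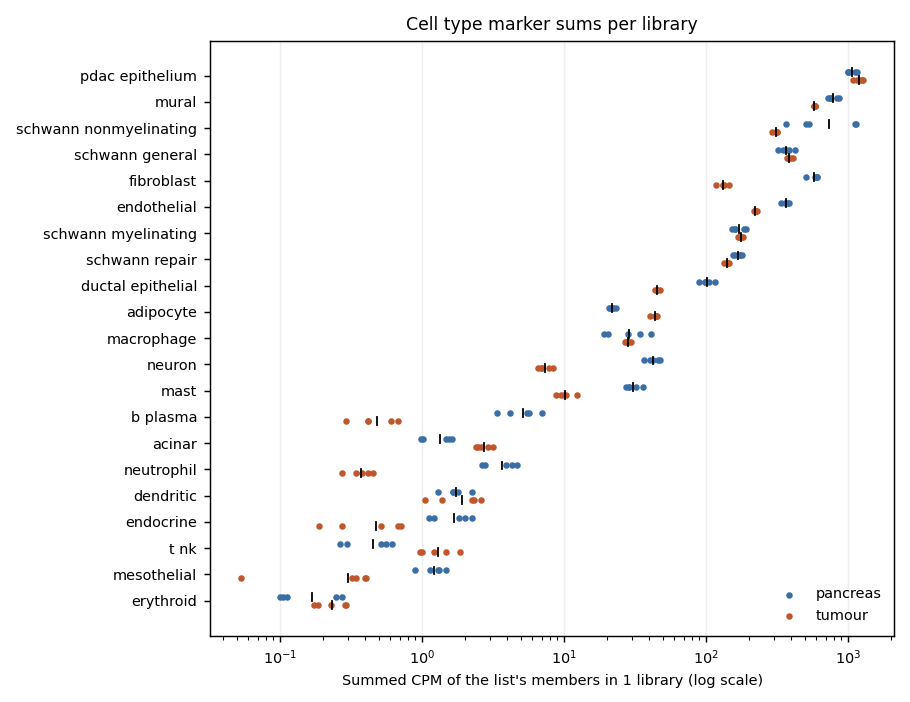
Summed CPM (log scale) of each cell type marker list, 1 point per library, with 5 pancreas and 5 tumour libraries per list and a black tick at each group mean. Fibroblast markers sit near 578 CPM in pancreas and 132 in tumour, while the Schwann lineage sums overlap at 368 and 386 CPM.

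Tested gene by gene, the fibroblast list had 8 members lower and 2 higher of 10 (median log2 fold change -1.68, camera adjusted p = 0.00463, adjusted p = 0.146 with an estimated correlation). The surface antigen gene Thy1 fell from 392 ± 25.2 to 3.99 ± 0.723 CPM and the collagen gene Col3a1 from 162 ± 30.6 to 42.8 ± 7.24, while the growth factor receptor gene Pdgfra was higher, at 12.4 ± 1.80 and 45.1 ± 3.35. Dcn had 0 counts in all tumour libraries and 273 in the pancreas libraries together. With the tumour group set to a floor of 3 counts it was 95.2-fold lower. That is no lower bound, since a sequenced fragment seems to add several counts. With Dcn at that value the list's median stayed at -1.68. The pericyte and smooth muscle list had 5 lower and 4 higher of 10 (median -0.38, adjusted p = 0.0104, adjusted p = 0.146 with an estimated correlation). The contractile genes Acta2 (266 ± 45.1 and 1.74 ± 0.153 CPM) and Tagln (41.8 ± 8.12 and 0.541 ± 0.228) were lower, and the proteoglycan gene Cspg4 was higher (171 ± 19.8 and 248 ± 4.58). The ductal epithelial list had 5 lower and 1 higher of 7 (median -0.95, adjusted p = 0.0440, adjusted p = 0.365 with an estimated correlation). The keratin gene Krt19 was at 34.7 ± 4.21 and 24.5 ± 1.54 CPM and the chloride channel gene Cftr at 54.6 ± 9.80 and 1.51 ± 0.255. This call ended when pancreas replicate 3 (adjusted p = 0.0796) or 4 (0.0668), or tumour replicate 1 (0.0574), 2 (0.0582) or 4 (0.0743) was left out, and with counts divided by 4 (0.116). Other marker lists were not shifted. Endothelial genes were 3 lower and 1 higher of 9 (adjusted p = 0.369), with Cdh5 at 333 ± 15.4 and 191 ± 4.45 CPM. Neoplastic epithelium genes were 2 and 2 of 7 (0.535), with Lcn2 at 461 ± 29.0 and 680 ± 50.9 and Msln at 630 ± 48.9 and 459 ± 33.9. The macrophage list had 2 higher and 1 lower of 4 (0.659), and the neuronal list 1 and 1 of 4 (0.428). The adipocyte list had 2 higher of 3 (0.181), and the endocrine (0.535) and mast cell (0.206) lists 2 lower of 3 each. In the acinar, B and plasma cell, dendritic, erythroid, mesothelial, neutrophil and T and natural killer cell lists fewer than 3 members could be tested.

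Across the transcriptome, 11542 of 17548 tested genes differed between tumour and pancreas (65.8%), 5689 higher and 5853 lower in tumour (edgeR quasi-likelihood test, adjusted p below 0.05). Of these, 2228 were higher and 1811 lower by at least 2-fold. The groups' CPM did not overlap for 9583 genes (54.6%), against 0.794% by chance. Libraries of the same group had Spearman correlations of 0.985 to 0.993 in pancreas and 0.992 to 0.994 in tumour, against 0.942 to 0.955 between groups. The first principal component, with 64.7% of the variance, separated the groups. The second, with 6.96%, set pancreas replicates 3 and 4 apart from pancreas replicates 1, 2 and 5. Variation between libraries was wider in pancreas (coefficient of variation 21.8%) than in tumour (12.2%). Scaling by library size alone moved the median log2 fold change of all genes by 0.10 and gave 6635 genes higher and 4986 lower. Nothing in the labels says whether libraries came from separate animals, so the p-values measure the spread between these samples, which may be technical.

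By fold change, the highest gene in tumour under the naming rule was Sel1l3 (98.0-fold, from 0.259 ± 0.212 to 25.2 ± 1.70 CPM). Spon1 encodes the secreted matrix protein F-spondin (ENSMUSG00000038156.16, chromosome 7, 113765998 to 114043370). It rose from 3.59 ± 1.03 to 254 ± 19.3 CPM (log2 fold change 6.15 ± 0.17, adjusted p = 1.9e-10). Also among the 10 highest were Fat4, an atypical cadherin (58.6-fold), Map7d2 (57.5-fold), Dpyd, the first enzyme of pyrimidine breakdown (52.8-fold), the proteoglycan gene Gpc3 (50.1-fold) and the transcription factor gene Onecut2 (48.4-fold). The list went on with the glutathione transferase gene Gsta3 (40.7-fold), the carbonic anhydrase gene Car6 (35.9-fold) and Cdsn (34.1-fold, 4.60 ± 0.983 to 156 ± 6.45 CPM). The lowest gene under the same rule, which asks for a mean of at least 5 CPM, was Gpx3, a secreted glutathione peroxidase (ENSMUSG00000018339.11, chromosome 11, 54902453 to 54910377). It fell from 105 ± 25.7 to 0.336 ± 0.174 CPM (log2 fold change -8.34 ± 0.27, adjusted p = 7.3e-10). Acta2 was 152-fold lower, Thy1 97.8-fold and Tagln 76.6-fold, and the water channel gene Aqp1 fell from 3253 ± 414 to 46.3 ± 9.91 CPM. Sfrp1, an inhibitor of Wnt signalling (64.5-fold), Adam33 (42.2-fold), Apod (36.1-fold), Cftr (35.8-fold) and the vascular growth factor gene Angpt2 (31.7-fold) were lower too. Trp53, which the model alters, was lower in tumour (181 ± 14.6 and 132 ± 4.20 CPM, log2 fold change -0.46 ± 0.05, adjusted p = 6.2e-06).

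Among lncRNA genes, 507 were higher and 262 lower in tumour of 1700 tested. Of the changed lncRNA genes 65.9% were higher, against 47.9% of the changed protein-coding genes (4636 higher, 5038 lower; odds ratio 2.10, 95% confidence interval 1.80 to 2.46, two-sided Fisher's exact test p = 3.9e-22). Genes are not independent replicates in that test. With at least 1 CPM required in 5 libraries, 268 lncRNA genes were higher and 142 lower. Pvt1, a lncRNA gene next to Myc (ENSMUSG00000097039.8, chromosome 15, 62037986 to 62378096), was 2.14-fold higher in tumour (28.6 ± 3.52 and 61.3 ± 4.60 CPM, log2 fold change 1.10 ± 0.08, adjusted p = 7.2e-08). Each of the 5 tumour libraries lay above every pancreas library. The largest increases under the rule were those of Gm49364 (30.8-fold), Gm17173 (26.3-fold), 2310069B03Rik (21-fold), 4930565N06Rik (20.1-fold, 0.874 ± 0.176 to 17.7 ± 2.05 CPM) and Gm20658 (17.1-fold). Gm49364 and Gm17173 overlap each other and Ptger2 on chromosome 14, so their increases cannot be counted as separate. The largest decreases were those of Gm15482 (60.4-fold), Gm20634 (55.5-fold, a gene overlapping histone genes), Snhg18 (18.2-fold), Gm49083 (13.9-fold) and C130021I20Rik (10.2-fold, 32.7 ± 2.03 to 3.21 ± 0.684 CPM). The log2 fold change of Gm20634, -5.79, was -5.06 without pancreas replicate 5 and -6.48 without tumour replicate 2, and that of Gm15482, -5.92, was -7.17 without tumour replicate 3. Of 37 tested members of the list of well known lncRNAs 16 were lower and 9 higher (camera adjusted p = 0.428). Among them were the imprinted genes H19 (2.44 ± 0.621 and 12.9 ± 1.28 CPM) and Peg13 (55.6 ± 4.58 and 27.3 ± 1.66).

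**Figure D2:**
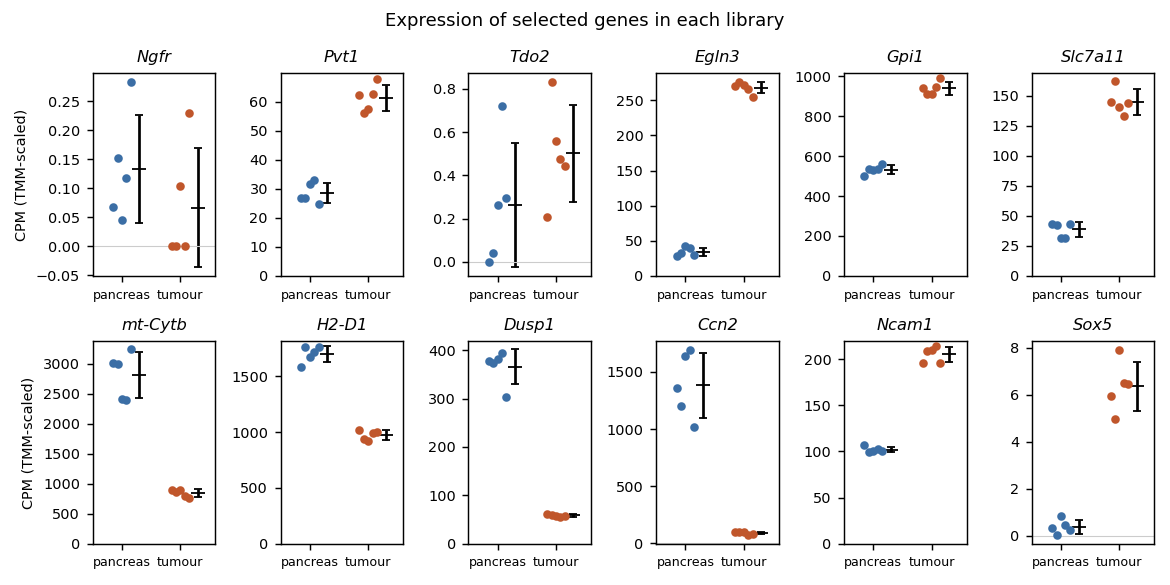
TMM-scaled CPM of 12 genes, 1 point per library and group, with black bars for mean ± SD over 5 libraries. Pvt1 runs near 28.6 CPM in pancreas and 61.3 in tumour without overlap, whereas Ngfr and Tdo2 stay below 1 CPM in all 10 libraries.

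Members of the kynurenine pathway, which breaks down tryptophan, were few and low. Of 6 tested, 2 were higher and none lower (median log2 fold change 0.48, camera adjusted p = 0.656). Tdo2 encodes a first enzyme of the pathway (ENSMUSG00000028011.16, chromosome 3, 81957090 to 81976202). It had 0 to 49 counts per pancreas library and 18 to 64 per tumour library, or 0.265 ± 0.287 and 0.503 ± 0.225 CPM, and did not pass (log2 fold change 0.91 ± 0.76, adjusted p = 0.306). The formamidase gene Afmid was higher (7.61 ± 1.38 and 16.3 ± 2.34 CPM, adjusted p = 8.6e-06). Ido1 passed narrowly (0.225 ± 0.0460 and 0.460 ± 0.207 CPM, adjusted p = 0.0412), and its call ended when any of pancreas replicates 1 (adjusted p = 0.0766), 2 (0.0730), 3 (0.0652) and 5 (0.0877) or tumour replicates 2 (0.0659), 3 (0.118) and 4 (0.105) was left out. It also ended without a low-count filter (adjusted p = 0.0868), with limma-voom (0.0886) and with the replicate block (0.0914). Genes of the aryl hydrocarbon receptor, which binds kynurenine, were 5 higher and 1 lower of 6 (median 0.99, adjusted p = 0.0131, adjusted p = 0.146 with an estimated correlation). The receptor gene Ahr itself (2.82 ± 0.186 and 5.83 ± 0.848 CPM), Tiparp (24.6 ± 0.758 and 84.9 ± 5.06) and the quinone reductase gene Nqo1 (55.6 ± 18.1 and 198 ± 15.3) were higher. Nqo1 is also counted below with targets of another regulator, Nrf2. Outside the naming rule, the lower member was the target gene Cyp1b1 (log2 fold change -1.33, adjusted p = 4.1e-04), and the target gene Cyp1a1 rose by 0.54. Without pancreas replicate 5 the list did not pass (adjusted p = 0.102). Amino acid transporters moved both ways, 4 higher and 5 lower of 11 (adjusted p = 0.990). The cystine transporter gene Slc7a11 was 3.75-fold higher (38.7 ± 6.21 and 145 ± 10.8 CPM), the cationic amino acid transporter gene Slc7a3 5.35-fold lower and the glutamine transporter gene Slc1a5 1.82-fold lower.

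Glycolytic genes were higher in tumour and mitochondrially encoded genes lower. Of 17 glycolysis genes 16 were higher and none lower (median log2 fold change 0.56, camera adjusted p = 1.2e-05, adjusted p = 0.210 with an estimated correlation). Among them were Gpi1 (532 ± 21.4 and 939 ± 32.1 CPM), Tpi1 (404 ± 36.2 and 712 ± 18.0), Pgk1 (618 ± 15.8 and 912 ± 22.8) and the hexokinase gene Hk1 (129 ± 4.30 and 191 ± 3.87). Hypoxia response genes were 8 higher and 2 lower of 13 (median 0.66, adjusted p = 4.5e-04, adjusted p = 0.443 with an estimated correlation). Among them the prolyl hydroxylase gene Egln3 was 7.77-fold higher (34.4 ± 5.91 and 268 ± 8.19 CPM, log2 fold change 2.96 ± 0.10), and Ero1l (2.99-fold), P4ha1 (2.64-fold) and the mitophagy gene Bnip3 (2.63-fold) were higher as well. All 13 mitochondrially encoded protein genes were lower (median -1.17, adjusted p = 2.2e-13, adjusted p = 0.210 with an estimated correlation). Examples were mt-Cytb (2815 ± 386 and 842 ± 62.6 CPM), mt-Nd4 (1857 ± 239 and 603 ± 46.2) and mt-Nd3 (112 ± 17.2 and 27.1 ± 2.99). Mitochondrially encoded genes together took 2.56 ± 0.236% of counts in pancreas and 1.42 ± 0.0712% in tumour (n = 5 each, exact permutation p = 0.00794, the smallest possible). Nuclear genes of the respiratory chain were 13 lower and 3 higher of 20 (median -0.30, adjusted p = 0.0386, adjusted p = 0.566 with an estimated correlation). Examples were Cox4i1 (358 ± 26.5 and 229 ± 3.43 CPM) and Cox7a2 (46.6 ± 3.65 and 26.2 ± 2.07). That call ended under library size scaling (adjusted p = 0.110), with the 1 CPM minimum (0.0785) and with counts divided by 4 (0.0651). Cholesterol synthesis genes split into 8 higher and 6 lower of 16 (adjusted p = 0.926), with Idi1 2.13-fold higher.

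Immediate early and heat shock genes, which tissue dissociation is known to induce, were lower in tumour. In this list 13 of 15 members were lower and none higher (median log2 fold change -1.29, camera adjusted p = 2.2e-10), and it was the one list of 40 that also passed with an estimated correlation (adjusted p = 0.0103). The phosphatase gene Dusp1 fell from 366 ± 35.5 to 58.7 ± 2.40 CPM, the chaperone genes Hspa1b from 35.7 ± 3.16 to 10.1 ± 0.963 and Dnajb1 from 79.4 ± 3.28 to 36.7 ± 2.19, and the cytokine signalling inhibitor gene Socs3 from 51.9 ± 3.81 to 21.2 ± 1.35. The different digestion of pancreas and tumour moves with this list in every library. Targets of the growth regulators YAP and TAZ were 7 lower and 2 higher of 10 (median -1.42, adjusted p = 0.00114, adjusted p = 0.518 with an estimated correlation). Ccn2 was 15.5-fold lower (1382 ± 287 and 88.9 ± 10.5 CPM), Ccn1 3.29-fold and Ankrd1 8-fold lower, and Ptpn14 1.95-fold higher. Genes induced by ERK signalling were 5 lower and 3 higher of 12 (adjusted p = 0.0857). The feedback inhibitor genes Dusp6 (59.7 ± 6.46 and 17.7 ± 1.07 CPM) and Spry2 (98.2 ± 14.2 and 33.1 ± 2.40) were lower. Targets of p53 were 9 lower and 1 higher of 13 (median -0.34, adjusted p = 0.0524), with Fas 2.31-fold and Bax 1.64-fold lower. That list passed without pancreas replicate 1 (adjusted p = 0.0238), 2 (0.0345) or 5 (0.0372) or tumour replicate 5 (0.0477). Stress response genes of the unfolded protein list were 7 lower and 3 higher of 12 (adjusted p = 0.718): Ddit3 (2.41-fold) and Trib3 (2.39-fold) were higher and Xbp1 1.72-fold lower.

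Genes for making ribosomes were lower in tumour. Of 14 ribosome biogenesis genes 13 were lower (median log2 fold change -1.01, camera adjusted p = 2.6e-05, adjusted p = 0.511 with an estimated correlation). They included the nucleolar protein genes Nop56 (221 ± 36.6 and 44.1 ± 2.23 CPM) and Nop58 (136 ± 19.8 and 64.7 ± 4.51) and the RNA polymerase I subunit gene Polr1b (50.6 ± 4.67 and 20.8 ± 0.940). The exception was Odc1, which makes polyamines and was 1.68-fold higher. Ribosomal protein genes were 19 lower and 1 higher of 22 (median -0.34, adjusted p = 5.0e-05, adjusted p = 0.524 with an estimated correlation), for example Rpl7a (818 ± 50.6 and 418 ± 8.19 CPM). As a class they took 5.99 ± 0.302% of counts in pancreas and 4.83 ± 0.0497% in tumour (n = 5 each, exact permutation p = 0.00794). The 50 most abundant genes took 12.6 ± 0.510% and 10.9 ± 0.122% (exact p = 0.00794). Cell cycle genes went 6 each way of 20 (adjusted p = 0.875), with the replication genes Pcna and Mcm5 1.63-fold and 1.70-fold lower. Replication-dependent histone genes, whose mRNAs lack a poly(A) tail, were 5 lower of 7 at low levels (adjusted p = 0.206).

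MHC class I genes, which present antigen to cytotoxic T cells, were lower in tumour in 10 of 12 cases and higher in none (median log2 fold change -0.65, camera adjusted p = 8.1e-05, adjusted p = 0.146 with an estimated correlation). The heavy chain gene H2-D1 fell from 1700 ± 72.7 to 974 ± 40.9 CPM, H2-T23 from 414 ± 53.4 to 214 ± 11.6, the immunoproteasome gene Psmb10 from 47.2 ± 4.59 to 19.2 ± 2.42 and the peptide transporter gene Tap1 from 160 ± 12.3 to 99.1 ± 3.47. Interferon-stimulated genes were 11 lower and 2 higher of 16 (median -0.59, adjusted p = 0.0120, adjusted p = 0.516 with an estimated correlation). Isg15 was 2.09-fold and Oas1a 2.39-fold lower, and Rsad2, an antiviral gene of the same list, was 4.00-fold higher. MHC class II genes were 2 higher of 5 (adjusted p = 0.569), with Cd74 at only 0.631 ± 0.170 and 1.69 ± 0.255 CPM. Immune checkpoint ligands and suppressive enzymes were 3 lower and 2 higher of 11 (adjusted p = 0.535). The costimulatory ligand gene Cd80 (210 ± 5.45 and 118 ± 3.81 CPM) and Lgals9 (196 ± 28.3 and 108 ± 3.17) were lower, and Cd276 was higher at a low level (0.529 ± 0.140 and 1.10 ± 0.316). Cytokine and chemokine genes were 8 higher and 8 lower of 17 (adjusted p = 0.533). The T cell attractant gene Ccl5 was 12.8-fold higher (2.74 ± 0.462 and 35.0 ± 6.50 CPM), the neutrophil attractant gene Cxcl2 2.37-fold and Tgfb1 2.02-fold higher (64.6 ± 14.7 and 130 ± 5.46), and Cxcl16 2.74-fold lower.

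Nerve growth and axon guidance genes were 7 lower and 1 higher of 12 (median log2 fold change -0.95, camera adjusted p = 0.0225, adjusted p = 0.365 with an estimated correlation). The receptor gene Ret fell from 35.6 ± 5.69 to 1.96 ± 0.399 CPM and the axon repellent gene Sema3a from 8.73 ± 2.83 to 0.645 ± 0.227. Matrix genes were 10 lower and 3 higher of 19 (adjusted p = 0.428). The laminin gene Lamc1 was 2.42-fold higher (330 ± 25.7 and 798 ± 18.9 CPM), Sparc was 1.65-fold lower, the collagenase gene Mmp13 was 8.52-fold lower, and tenascin C (Tnc) had 7.12 ± 2.27 CPM in pancreas and 0 to 5 counts per tumour library. The 5 sex-linked genes went 1 each way (adjusted p = 0.990).

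**Figure D3:**
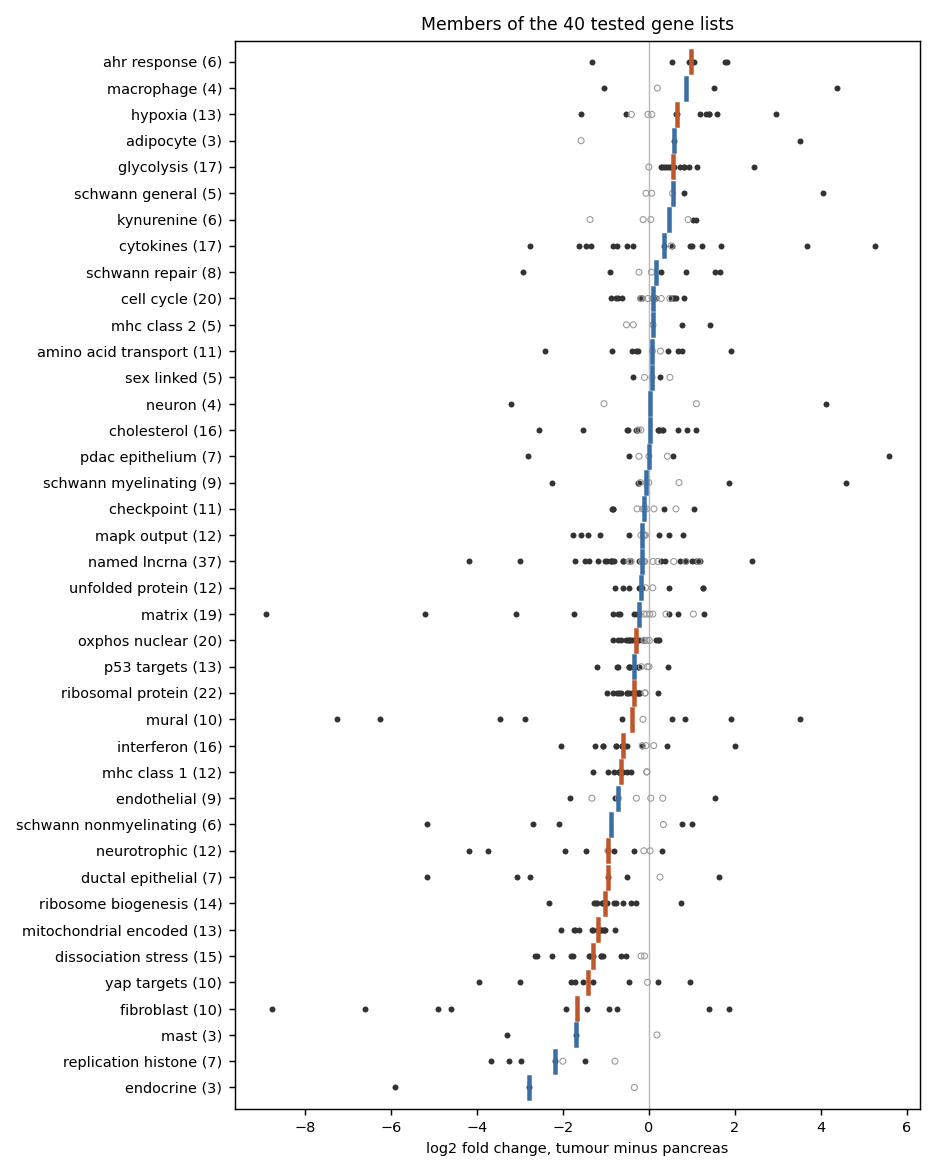
Log2 fold change, tumour minus pancreas, of every tested member (filled points past an adjusted p of 0.05, open points not) of the 40 tested lists, with the number of tested members in brackets and a bar at each median, orange where camera passed 0.05 and blue where not. Medians of the shifted lists run from -1.68 for fibroblast genes to 0.99 for aryl hydrocarbon receptor genes, and the leftmost fibroblast point is the fitted value of Dcn, which had 0 tumour counts.

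Of 40 lists 3 were shifted higher and 12 lower by camera with its preset correlation, and 0 higher and 1 lower with an estimated one. Counts of members adjusted over the list alone equalled those over all tested genes except for cell cycle (6 higher, 4 lower), kynurenine (1 higher) and repair Schwann genes (4 higher, 3 lower). Median, mean and camera direction also differed in sign for the cell cycle, amino acid transport, cholesterol, neuronal, unfolded protein and sex-linked lists, of which none passed. Exons of Pvt1, Fat4, Tagln, Cftr, Gm49364, Gm17173, Gm15482, Gm20634, H19, Sox5, Ncam1, Jun, Bdnf, Pdgfra, Col3a1, Afmid, Ahr, Tiparp, Gpi1, Hk1, Tpi1, Bnip3, Cox4i1, mt-Nd4, Idi1, Dusp1, Ccn2, Ptpn14, Bax, Ddit3, Nop56, Nop58, Rpl7a, Tap1, Cd74, Cd276, Cxcl16 and Tnc overlap an exon of another gene. The library kit does not mark strand, so their levels are uncertain to the extent that reads of the neighbour were counted. The same holds for genes with near-identical copies elsewhere, such as Hspa1b, H2-D1, Oas1a, the histone genes and the ribosomal protein genes.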

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

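In 356 sets of 5 library values (total counts, shares of counts, marker sums and the CPM of named genes, per group), 21 had 1 library set apart, its gap to the nearest other library being over 0.71 of the group's range. That is 5.90% of the sets, and chance sets apart about 1 in 20. Of the 21, 7 fell on tumour replicate 5, the shallowest library, and 3 each on tumour replicate 2 and pancreas replicate 5. No explanation was tested for these values.

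Among marker sums, fibroblast markers stood at 507 CPM in pancreas replicate 5 against 584 to 603 in the other pancreas libraries (gap ratio 0.809), mesothelial markers at 0.0530 CPM in tumour replicate 4 against 0.322 to 0.401 (0.773), and non-myelinating Schwann markers at 292 CPM in tumour replicate 5 against 313 to 318 (0.813).

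Tumour replicate 5 was also low for Nqo1, at 171 CPM against 200 to 211 (gap ratio 0.726), and G6pdx, at 63.8 against 76.5 to 80.6 (0.758). It was high for Gpx3, at 0.643 against 0.207 to 0.286 (0.820), Tiparp, at 93.6 against 81.4 to 84.8 (0.721), Ddit3, at 150.3 against 124 to 132 (0.714), and Ccl5, at 46.2 against 29.3 to 34.0 (0.718). Tumour replicate 2 was low for Gm49364, at 1.71 CPM against 4.12 to 4.66 (0.816), high for Pgk1, at 952 against 894 to 907 (0.772), and the only tumour library with counts of Tnc, at 0.0648 CPM (ratio 1). Tumour replicate 3 was low for Gsta3, at 16.9 against 20.5 to 21.6 (0.773), and Pmp22, at 106 against 112 to 115 (0.713), and tumour replicate 1 was high for Mcm5, at 45.0 against 39.7 to 41.2 (0.711).

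In the pancreas group, replicate 5 was high for Gm20634, at 20.9 CPM against 3.69 to 5.89 (gap ratio 0.872), which accounts for the wide SD of that gene, and low for Dusp1, at 304 against 373 to 394 (0.774). Pancreas replicate 3 was high for C130021I20Rik, at 36.2 against 31.2 to 32.6 (0.711), and Idi1, at 5.03 against 3.07 to 3.45 (0.808). Pancreas replicate 1 was low for Bax, at 181 against 216 to 230 (0.715), and pancreas replicate 4 for Cd74, at 0.339 against 0.648 to 0.771 (0.715).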

How the results depend on the processing

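The alternatives dividing counts by 4 and offsetting GC content and length were chosen after seeing the data. Genes changed stayed within 1.5 times the reported counts of 5689 higher and 5853 lower under each alternative to scaling, filter, test or false discovery rate, from 4783 to 6635 higher and 4925 to 6102 lower. Asking for at least 2-fold left 2228 and 1811, since fewer genes are that far apart. With at least 1 CPM in 5 libraries fewer lncRNA genes were tested, and 268 were higher and 142 lower. The lncRNA odds ratio ran from 1.91 to 2.54. Leaving out 1 library gave 5445 to 5749 genes higher and 5628 to 5848 lower, 474 to 537 lncRNA genes higher and 240 to 261 lower, an odds ratio of 2.02 to 2.37, 2 to 3 lists higher and 11 to 13 lower, and 3 to 4 marker sums higher and 12 lower.

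Of the 15 shifted lists, 0 higher and 1 lower held with an estimated correlation. For some lost lists that estimate was far above the preset 0.01. It was 0.829 for mitochondrially encoded, 0.809 for ribosome biogenesis, 0.798 for YAP and TAZ target and 0.669 for ribosomal protein genes. For others it was near the preset (fibroblast 0.0319, aryl hydrocarbon receptor -0.0197), and why these were lost was not tested. Fry, which asks only whether members move one way, gave 11 higher and 22 lower, and the cause was not tested. Over the alternatives tested with camera, oxidative phosphorylation ran from adjusted p = 0.0221 to 0.566, aryl hydrocarbon receptor genes from 0.0103 to 0.146, ductal genes from 0.00682 to 0.365 and p53 targets from 0.0238 to 0.566. Of 151 genes tested under the alternatives, with genes chosen after their values were seen, Ido1 (0.0174 to 0.118), Pmp22 (9.3e-04 to 0.0758) and Zmat3 (5.5e-16 to 0.0556) lost their call under some alternative. In comparisons with an alternative, named genes kept direction and call 2996 times, lost the call 12 times, gained it 1 time and turned 2 times. The gain was Ddx3y (-0.55 with GC content and length offsets, adjusted p = 7.1e-07, range to 0.968). Both turns came with those offsets. They were Malat1 (-0.0512, adjusted p = 0.635, so no longer called) and Cryab (0.17, adjusted p = 0.0215, range to 0.912), and neither cause was tested. Lists kept, lost and gained it 624, 24 and 22 times, and marker sums 266, 17 and 5 times.

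Without its most abundant member, 6 marker sums in place of 3 were higher. The log2 difference then turned for acinar (-0.0768), neuronal (0.88), neoplastic epithelium (-0.31), non-myelinating Schwann (0.98), repair Schwann (0.13) and T and natural killer cell markers (-0.25) since the member left out had set the direction of the sum. The ratio turned but did not pass for acinar (exact adjusted p = 0.706) and repair Schwann markers (0.176).

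The labels number replicates 1 to 5 in both groups without saying that the numbers pair samples. Deviations of same-numbered libraries correlated at -0.02 to 0.04, and 1 of 5 pancreas and 0 of 5 tumour libraries correlated best with its own number, so the numbers do not pair them. With the replicate block, 5587 genes were higher and 5598 lower, 489 and 236 lncRNA genes (odds ratio 2.20) and 3 and 12 lists. The blocked sign-flip test of marker sums called 0 higher and 0 lower, since its smallest p with 5 pairs is 0.0625. The depth in fragments is unknown, so the precision that depth gives for low genes, Ngfr and Tdo2 among them, was not measured.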

Other observations

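The tests of the genes near the floor and of tissue digestion were chosen only after the results were seen, as were the extra gene lists, and the genes named here outside the naming rule were chosen after their values were seen. Further targets of Nrf2, a regulator of antioxidant genes, were higher in tumour: 11 of 18 genes that no other list held were higher and 3 lower (median log2 fold change 0.50, camera p = 1.1e-05, but p = 0.0901 with an estimated correlation). Srxn1 went from 145 ± 18.5 to 608 ± 29.5 CPM, Gclm from 112 ± 21.7 to 517 ± 29.0, Txnrd1 from 425 ± 27.5 to 1151 ± 36.2 and Abcc1 from 273 ± 6.02 to 780 ± 11.7 (SD, n = 5), while G6pdx was lower (127 ± 10.6 and 75.6 ± 6.77). With Nqo1, Slc7a11 and Gsta3 these values are consistent with higher Nrf2 activity in tumour, as a hypothesis found and tested on the same data. Lysosomal genes were examined because cathepsin genes were among the most abundant, and did not shift as a group: 9 of 20 were higher and 5 lower (median 0.06, camera p = 0.0866, and p = 0.615 with an estimated correlation). Myc, the neighbour of Pvt1, was lower in tumour (140 ± 23.6 and 65.1 ± 3.75 CPM, log2 fold change -1.10 ± 0.10) while Pvt1 was higher.

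Other splits of the 10 libraries into 5 and 5 were tested in 100 of 126 possible splits. Only 1 of 100, the real one, called as many genes (11542, highest other 1) or lncRNA genes (769, highest other 1). The real division therefore stood apart from the other tested splits for both counts. Each of those mixes libraries of both groups, so the wide separation of the groups largely fixed this outcome in advance. Whether each library came from a separate animal is unknown, so a chance difference between the sources of the groups cannot be excluded. For lists too, 1 of 100 splits shifted as many as the real 15, and the others shifted 0 to 13 (median 6). That sets the count of 15 apart from those of the other splits but does not test any single list. Of the 15, 1 passed with an estimated correlation. Every other split puts 3 or 4 libraries of a group together and keeps part of the difference between the groups, so its lists are not a count of false calls.

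Ngfr, on whose product the cells were sorted, was near the floor in all libraries, as were Sox10 (at most 9 counts), S100b (at most 20) and Foxd3 (0) of the Schwann lineage list, while Cryab of that list was at 377 ± 37.2 CPM in pancreas and 361 ± 17.0 in tumour (SD, n = 5). Shallow libraries do not account for this, since each had at least 21963 genes with a count and low depth widens the spread of CPM without lowering their mean. Mostly cells of another listed type cannot be told apart from cells of the Schwann lineage. The highest median over the members of such a list was 3.73 CPM, for pericyte and smooth muscle genes in pancreas. Every member of the Schwann lineage list but Cryab lay below that in pancreas, the next being Erbb3 at 2.10 CPM. A low median therefore does not argue against another listed type. In addition, 10 members of the lists of other types were over 50 CPM in a group, led by Lcn2 (680), Msln (630), Thy1 (392) and Cdh5 (333). All 10 libraries had the Y-linked gene Ddx3y at 48.2 to 57.5 CPM and Xist at 0.0965 to 0.719 CPM. A single cultured male source would give this (the code COCUL could stand for co-culture), but so would male mice in every sample. Ddx3y and Xist therefore cannot tell these apart. Acinar genes summed to only 60 to 266 counts per library, and 7 of 20 had 0 counts in all libraries. Cultured cells and a clean sort would both give low acinar counts, so culture of the cells stays open. A cell type outside the lists, low Ngfr mRNA in cells that carry the protein and a change of such cells in tumour remain open and untested.

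Immediate early and heat shock genes had a median log2 fold change of -1.29 in tumour. Digestion differed between the groups in every library, so its effect and that of the tumour cannot be told apart. A candidate explanation is lower activity of serum response factor, which drives several of these genes. Its own gene Srf and its cytoskeletal targets that no fixed list held were 13 lower and 1 higher of 17. The median was -0.56, the value of Srf itself (camera p = 3.2e-04, but p = 0.233 with an estimated correlation). Flna went from 1609 ± 178 to 695 ± 47.1 CPM and Cnn2 from 412 ± 80.6 to 212 ± 3.41 (SD, n = 5). That fits the explanation, but digestion could lower these targets too, and pericyte and smooth muscle markers, whose cells the sort on the NGFR protein is meant to remove, moved both ways: Acta2 (log2 fold change -7.25), Tagln (-6.26), Cnn1 (-3.47), Rgs5 (-2.88) and Pdgfrb (-0.625) fell, while Des (3.52), Myh11 (1.91), Notch3 (0.84) and Cspg4 (0.54) rose.

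Changed lncRNA genes were higher in tumour more often (65.9%) than changed protein-coding genes. Low abundance does not account for it: protein-coding genes drawn to match on mean CPM were higher in 50.3% (95% range 46.8 to 53.8 over 10000 draws). Nor do reads from exons of overlapping genes. Of the 353 changed lncRNA genes with no exon overlap 71.1% were higher (Fisher's exact p = 5.2e-18). Genes lying inside introns of other genes stayed in that set, so unspliced reads of a host gene were not excluded. More unspliced or nuclear RNA in the tumour libraries stays open: the 1066 tested genes of other biotypes wholly inside an intron of a protein-coding gene had a median log2 fold change of 0.39 (95% bootstrap interval 0.29 to 0.49), but of the nuclear RNAs Malat1 was higher (1313 ± 179 and 1710 ± 138 CPM, but log2 fold change -0.0512 with GC content and length offsets) and Neat1 lower (2259 ± 313 and 1155 ± 99.6). The genes inside introns include lncRNA genes, so their median is not independent of the pattern. A change of lncRNA transcription in tumour also remains open.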
